A study of Homo sapiens with 8 samples.

How the data were processed

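RNA sequencing had been carried out on human umbilical artery endothelial cells (HUAECs), cultured for 5 days either in complete endothelial growth medium (control, 4 libraries, whose treatment label is "BSA") or in a medium that induces endothelial-to-mesenchymal transition (TGFbeta, 4 libraries). Per the labels, RNA was isolated with an RNeasy Plus kit and libraries were made with a SMARTER mRNA-Seq kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Knockdown of ACSS2, which the series description names, was not analysed here.

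The authors deposited expected counts, per the values of the file: estimated reads per transcript model and library, fractional where reads had been divided between overlapping models, with a sum of at least 10 over the libraries in every row. The authors also deposited CPM values (each library scaled to the same total) per transcript model, to which 0.0001 had been added and which had not been divided by transcript length, as the values show. STAR and edgeR are named without version or role, per the submitters' processing notes. The counting tool, annotation, strand setting and genome build are not given in the sources used here. Positions are those of the deposited tables, counted from 1 with the last base included; 1 was taken from the stop column, which lay 1 past the last base in 20 of 20 mitochondrial genes compared with an annotation. Positions on the nuclear chromosomes run past the last annotated base of GRCh38 on 14 chromosomes, so no coordinate or annotation of that build was used beside them. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Genes with near-identical paralogs or pseudogenes are uncertain to the extent that the counting divided their reads.

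Transcript values were summed by gene symbol. Older symbols were replaced by the current symbol where that was unique and on the same chromosome (1064 symbols in the expected counts and 385 in the CPM values). Transcripts whose symbol had been turned into a date (170 models with 0.225% of all expected counts) could not be named. Genes found only on the Y chromosome and XIST were left out. Libraries held 17970603 to 21622143 expected counts. Replicate libraries differed by more than sampling noise in each of 12 pairs (chi-square per degree of freedom 1.92 to 4.54), so no library was a second copy of another; this does not show that they came from separate cultures.

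The design, the 30 gene lists, the rule for named genes and most other settings were fixed before the data were examined. The expected counts were chosen over the CPM values once the units of both were known. They were rounded to whole numbers, filtered with filterByExpr (minimum count 10), scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest), with the group as the only term. The test was two-sided, with Benjamini-Hochberg adjustment over 14684 genes and a threshold of 0.05. Levels are normalised CPM (counts per TMM-scaled library size) as mean ± SD. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Transcripts were tested in the same way. CPM values as deposited were tested with limma 3.58.1 on log2(value + 1), with a mean-variance trend and robust moderation, where at least 4 libraries reached 1 CPM; a fold change on that scale understates the change of low genes. PECAM1 is reported from the CPM values.

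Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with fry beside it. Fry does not compare a list with other genes. Unless fry is named, a list passed or did not pass by camera. Where a range over all alternatives is given for a list, its lower end is the fry value. Of 529 listed genes 477 were tested. The count of changed members adjusted over the list alone equalled that over all genes in 29 lists, and was 19 for glycolysis, whose count over all genes was 1 lower. The rule for named genes took the 8 largest rises and 8 largest falls in log2 fold change among genes that passed the test, had no overlap between the groups and had a mean over all libraries of at least the median of tested genes (19.4 CPM). Genes near 0 in the other group, such as LYVE1 and GXYLT2, can miss this bound despite a larger change. It added the up to 3 members of each list with the smallest p, and 14 genes chosen from the study's topic. Any other gene, such as a member named for going against its list, was chosen after its values were seen.

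Other settings fixed beforehand were the replicate number as a block, each library left out, no filter and a filter 5 times stricter, DESeq2 size factors, the DESeq2 1.42.0 Wald test, a fold change of at least 2, and an estimated correlation and fry for the lists. For the CPM values they were pseudocounts of 0.1 and 5, quantile normalization, median-ratio scaling, array weights and no trend. Exact permutation tests, tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A gene with no control read was compared with a floor of 3 counts over the group. Genes with 1 to 3 control reads have a ratio with an exact binomial 95% interval. Intervals and floors cover counting error only.

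The tests were tried on counts simulated from the real means, library sizes and dispersions of this comparison, with 200 features changed. The changed features, 50 for each fold change, left out the least abundant ones, so recovery of changes in those was not tried. Over 14516 genes, edgeR recovered 86% of 1.25-fold, 98% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes, and 7.25% of its calls were unchanged genes. Over 41024 transcripts it recovered 4%, 14%, 34% and 58%, with 3.51% of calls false. Camera called 0 of 100 random lists. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. Far fewer genes were changed than in the real comparison, so the scaling was not tried under so broad a change.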

Results

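The transcriptomes of HUAECs, endothelial cells of the umbilical artery, were compared after 5 days in control medium or in the medium that induces endothelial-to-mesenchymal transition (TGFbeta group), with 4 libraries per group. Control libraries held 18860935 to 21622143 expected counts and TGFbeta libraries 17970603 to 21093059 (exact permutation test of the means, two-sided p = 0.571). Correlations of log expression across genes were 0.991 to 0.994 within groups and 0.901 to 0.908 between them. The 10 most abundant genes took 12.2 ± 0.177% of counts with TGFbeta and 5.71 ± 0.0559% in controls (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allow).

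TGFbeta treatment was accompanied by higher matrix and contractile transcripts, lower cell cycle transcripts and endothelial markers that moved apart. FN1, which encodes fibronectin, rose 8.66-fold, from 4405 ± 115 to 38158 ± 1189 normalised CPM (SD, n = 4 per group). TAGLN, a smooth muscle actin-binding protein, rose 114-fold, from 20.7 ± 1.40 to 2369 ± 43.4 CPM, while ACTA2, smooth muscle alpha-actin, stood at 10.6 ± 0.845 and 10.7 ± 1.06 CPM (edgeR adjusted p = 0.962). MMP1, an interstitial collagenase, was 17.8-fold lower, and the proliferation marker MKI67 fell from 626 ± 19.6 to 159.5 ± 7.26 CPM. Of 14684 genes, 5547 rose and 5473 fell (edgeR quasi-likelihood test), and 1708 rose and 1416 fell by at least 2-fold.

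**Figure D1:**
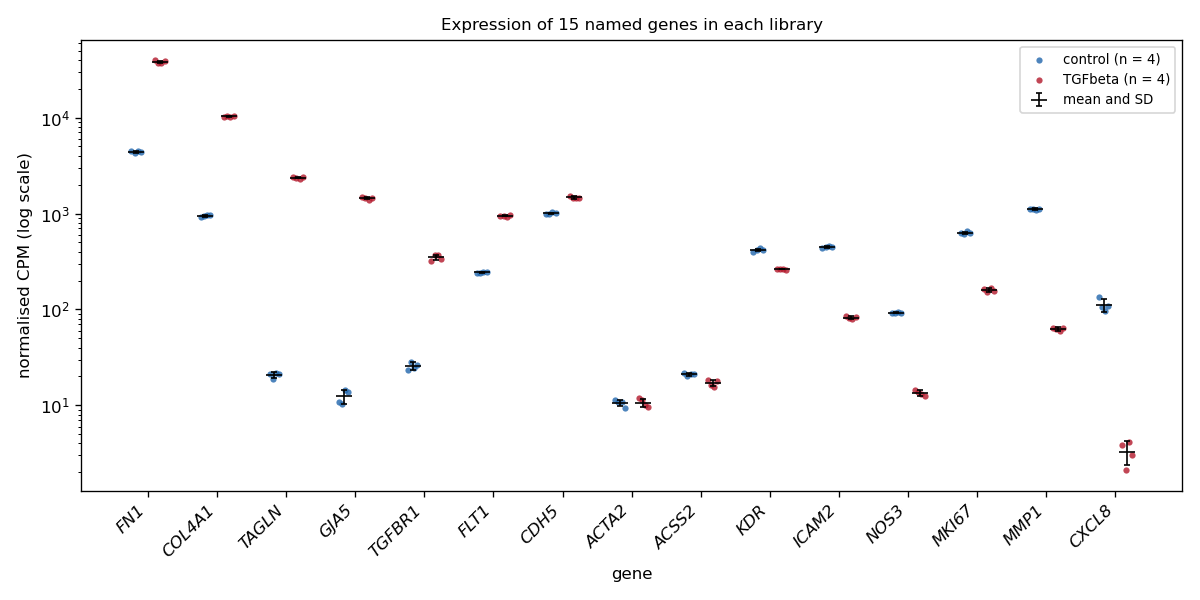
Normalised CPM (log axis) of 15 named genes in each library, with 4 points per group and black marks for the mean and SD. FN1 and TAGLN lie higher in all TGFbeta libraries, MKI67 and MMP1 lower, and ACTA2 overlaps between the groups, with means of 10.6 and 10.7 CPM.

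The balance of rises and falls depended on the scaling of the libraries. Library totals without TMM moved the median log2 fold change by -0.32, with 3320 genes higher and 8388 lower (28.4% of calls higher, against 50.3% with TMM). The deposited CPM gave 3003 higher and 7552 lower (limma). Changes below are relative to the TMM scale.

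Among genes with a mean of at least 19.4 CPM over all libraries, the largest rises included genes with almost no control reads. VCAN, which encodes the matrix proteoglycan versican, had 1 read over the 4 control libraries and 20702 to 23089 in each TGFbeta library (1261 ± 36.5 CPM), a ratio of 114036 with a 95% counting interval of 20467 to 4504220. CNN1, the smooth muscle protein calponin, had 1 control and 3719 TGFbeta reads (ratio 4776, interval 857 to 188707). For BDKRB2, a bradykinin receptor, these were 2 and 4288 (ratio 2754, interval 762 to 22744). FBLN5, an elastic fibre protein, rose from 3.27 ± 0.0682 to 950.1 ± 23.2 CPM (log2 fold change 8.18 ± 0.041 SE, edgeR adjusted p = 9.65e-30). TNC, a matrix glycoprotein (8.79 ± 0.097), DACT1 (8.74 ± 0.14), the chemokine gene CXCL12 (7.83 ± 0.14) and the transcript RP11-865I6.2 (7.74 ± 0.12) were the others.

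Among genes with that mean, the largest falls included secreted and surface proteins. DPP4, a membrane peptidase, fell from 89.4 ± 4.00 to 0.977 ± 0.234 CPM (log2 fold change -6.50 ± 0.088 SE, edgeR adjusted p = 2.94e-23). The neutrophil-attracting chemokine genes CXCL6 (-6.48 ± 0.13) and CXCL8 (-5.08 ± 0.13) fell, as did CDCP1 (-6.47 ± 0.12) and the nuclear receptor gene NR5A2 (-5.68 ± 0.086). The guidance cue gene SEMA3A (-4.32 ± 0.076), MMP1 (-4.15 ± 0.029) and MALL (-4.12 ± 0.052) completed the group.

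Targets of TGFbeta signalling rose together, in 23 of 23 tested cases (camera adjusted p = 2.75e-45, and adjusted p = 0.000599 with an estimated correlation). TGFBI, a secreted matrix protein, rose 19.1-fold, from 208 ± 4.60 to 3979 ± 34.3 CPM (log2 fold change 4.26 ± 0.024 SE, n = 4 per group). PMEPA1 (4.18 ± 0.030), ADAM19 (3.68 ± 0.028) and SMAD7, an inhibitor of the same pathway (3.63 ± 0.094), rose as well. Of 22 receptors, ligands and SMADs 14 rose and 7 fell (camera adjusted p = 1.80e-06, and adjusted p = 0.00747 with an estimated correlation), or 11 and 9 with library totals. In the CPM values this list did not pass after quantile normalization (adjusted p = 0.0662) or median-ratio scaling (adjusted p = 0.0533). The range over all alternatives was 1.68e-10, by fry, to 0.0662. The receptor gene TGFBR1 rose 13.6-fold, from 25.8 ± 2.27 to 349.9 ± 23.4 CPM, and INHBA, an activin subunit (4.58 ± 0.045), LTBP1 (3.87 ± 0.032) and TGFB2 (3.12 ± 0.042) rose too. The activin antagonist gene FST (-2.37 ± 0.042) and the co-receptor gene TGFBR3 (-2.30 ± 0.091) were among those that fell. BMP targets rose in 9 of 10 cases and SMAD9 fell (camera adjusted p = 0.0106, and adjusted p = 0.0796 with an estimated correlation). They included SMAD6 (2.99 ± 0.090), ID3 (1.02 ± 0.034) and the BMP antagonist gene GREM1, with 0 control and 988 TGFbeta reads, at least 423-fold higher against the floor.

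Matrix, smooth muscle and mesenchymal genes rose in most tested cases. All 29 tested members of the list of collagens and matrix proteins rose (camera adjusted p = 8.14e-93, and adjusted p = 0.00228 with an estimated correlation). Among them COL4A1, a basement membrane collagen, rose from 947 ± 16.9 to 10288 ± 109.6 CPM. The list does not hold every collagen: of 25 tested collagen genes 21 rose and COL4A5 (-1.78 ± 0.040 on the log2 scale), COL4A6 (-5.44 ± 0.099), COL13A1 (-2.17 ± 0.080) and COL17A1 (-3.63 ± 0.16) fell. Fibroblast and mesenchymal markers rose in 14 of 15 tested cases, ACTA2 being the exception (camera adjusted p = 1.44e-29, and adjusted p = 0.000443 with an estimated correlation). THY1, DCN and LUM, also on this list, were not tested. Some risers stayed low with TGFbeta: S100A4 (1.10 ± 0.447 CPM), PDGFRA (1.37 ± 0.180), PDGFRB (3.26 ± 0.559) and COL3A1 (5.07 ± 0.338). Others, such as FAP (165 ± 2.05 CPM) and POSTN (150 ± 2.61 CPM), reached higher levels. Of this list 10 members stand in another list. COL1A2, a fibrillar collagen chain, rose by 7.41 ± 0.060 on the log2 scale and FBN1, which encodes fibrillin, by 3.45 ± 0.027. Smooth muscle contractile genes rose in 13 of 15 cases and SMTN fell (camera adjusted p = 9.73e-30, and adjusted p = 0.000443 with an estimated correlation). TPM1, a tropomyosin (3.42 ± 0.027), and MYL9, a myosin light chain (3.80 ± 0.033), were among the risers. ACTA2 passed as lower with library totals (-0.32, edgeR adjusted p = 0.00248). MYH11, the smooth muscle myosin heavy chain, was below the filter, at 0.153 ± 0.0906 CPM with TGFbeta. The median log2 fold changes of the smooth muscle list (2.66) and the matrix list (3.08) hold also with genes of at most 3 control reads at their bound, since these stay above the median.

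Genes of matrix crosslinking and proteolysis went both ways, 13 up and 7 down of 24 (camera adjusted p = 0.0284, and adjusted p = 0.204 with an estimated correlation). MMP2, a gelatinase, rose by 4.08 ± 0.034 and the lysyl hydroxylase gene PLOD1 by 2.18 ± 0.024, against the fall of MMP1. The list did not pass with library totals (adjusted p = 0.0961), or in the CPM values after quantile normalization (adjusted p = 0.281) or median-ratio scaling (adjusted p = 0.0858; range over all alternatives 6.28e-08 to 0.281). Integrin and focal adhesion genes rose in 19 of 22 cases (camera adjusted p = 1.14e-13, and adjusted p = 0.00892 with an estimated correlation). The risers included the fibronectin receptor subunit ITGA5 (2.32 ± 0.023) and ITGB3 (2.06 ± 0.029). The laminin receptor subunit ITGA6 (-1.83 ± 0.023), ITGA2 and PXN fell. Of 16 YAP and MRTF-SRF targets 12 rose, among them ANKRD1 (2.17 ± 0.033) and CCN2 (1.67 ± 0.020), and LATS2, TRIB1 and AXL fell (camera adjusted p = 5.02e-11, and adjusted p = 0.0280 with an estimated correlation).

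**Figure D2:**
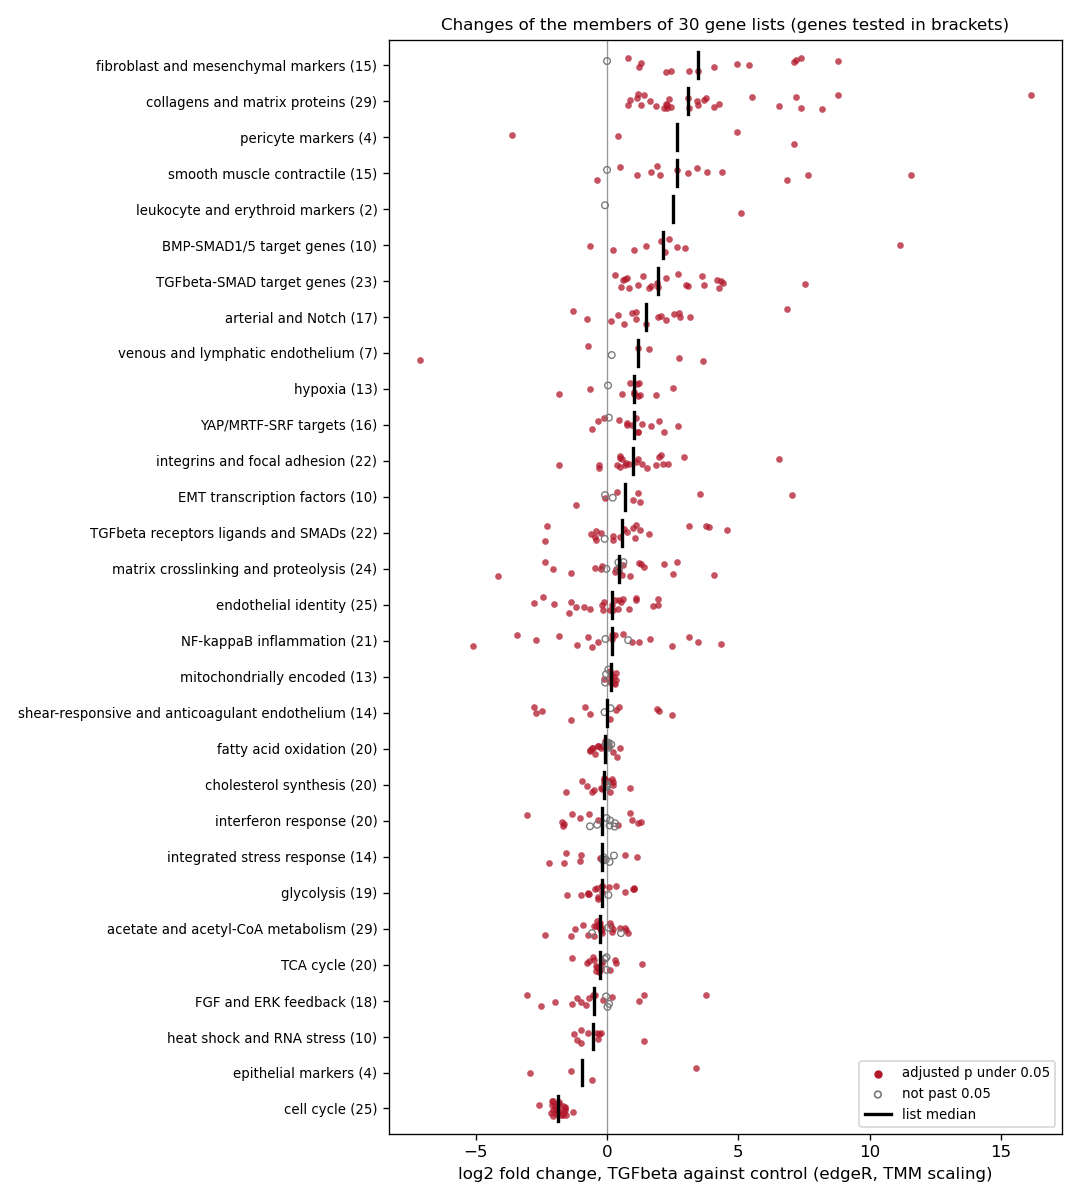
Log2 fold changes (TGFbeta against control, edgeR with TMM scaling) of the tested members of 30 gene lists, with 1 point per gene, filled where the adjusted p was under 0.05, and a bar at each list's median. The cell cycle list lies below 0 (median -1.85), the matrix list above it (median 3.08) and the endothelial identity list on both sides; library totals lower each value by about 0.32 and turn the medians of the endothelial identity, NF-kappaB, shear-responsive and mitochondrial lists below 0.

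Transcription factors of epithelial-to-mesenchymal transition rose in 6 of 10 tested cases, ZEB1 and HMGA2 fell, and the list did not pass (camera adjusted p = 0.0770). The fall of ZEB1 was slight (-0.085 ± 0.032 on the log2 scale, edgeR adjusted p = 0.0230). TWIST1, TWIST2, PRRX1 and LEF1, also on the list, were not tested. SNAI1 rose by 3.53 ± 0.082 on the log2 scale and TCF4 by 1.27 ± 0.033, against -1.18 ± 0.040 for HMGA2. SNAI2 had 2 control and 263 TGFbeta reads, a ratio of 169 (interval 46.3 to 1402). The list passed without a filter (adjusted p = 0.0380) and in the CPM values (adjusted p = 0.0267). The range over all alternatives was 1.46e-07, by fry, to 0.176. In the CPM values it did not pass after quantile normalization (adjusted p = 0.0881), median-ratio scaling (adjusted p = 0.0858) or the stricter filter (adjusted p = 0.0662).

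Endothelial identity genes moved apart, 14 up and 11 down of 25 (camera adjusted p = 0.950), or 10 up and 14 down with library totals. The VEGF receptor gene FLT1 rose 3.89-fold, from 243 ± 3.71 to 946 ± 13.0 CPM, and CDH5, which encodes VE-cadherin, rose from 1009 ± 14.5 to 1471 ± 43.7 CPM. PECAM1, an endothelial junction protein, rose from 522 ± 20.5 to 851 ± 17.8 deposited CPM (limma adjusted p = 4.47e-18). NOS3, endothelial nitric oxide synthase, fell from 92.1 ± 1.15 to 13.4 ± 0.878 CPM, ICAM2 from 449 ± 7.47 to 82.3 ± 2.86 CPM and the VEGF receptor gene KDR from 416 ± 13.1 to 264 ± 2.34 CPM. In the CPM values CDH5 turned to -0.087 on the log2 scale after quantile normalization.

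Arterial and Notch genes rose in 15 of 17 cases, and NRP1 and BMX fell (camera adjusted p = 2.45e-10, and adjusted p = 0.104 with an estimated correlation). GJA5, an arterial connexin, rose 117-fold, from 12.4 ± 2.11 to 1442 ± 39.0 CPM, and the Notch ligand gene JAG1 (2.05 ± 0.030) and the ephrin gene EFNB2 (1.93 ± 0.029) rose too. Of 7 venous and lymphatic genes EPHB4, FLT4 (3.64 ± 0.069), NRP2 (1.62 ± 0.030) and RELN (2.74 ± 0.080) rose, and NR2F2 and LYVE1 (-7.13 ± 0.23) fell (camera adjusted p = 0.0187, and adjusted p = 0.239 with an estimated correlation). This list did not pass in the CPM values (adjusted p = 0.0589), except with a pseudocount of 5 (adjusted p = 0.0467; range over all alternatives 7.48e-07 to 0.281). Shear-responsive and anticoagulant genes split, 6 up and 6 down of 14 (camera adjusted p = 0.603), or 4 up and 7 down with library totals. EDN1, which encodes endothelin, rose by 1.99 ± 0.023, and NQO1, a quinone reductase, changed by -2.45 ± 0.030.

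Inflammatory genes did not pass as a group. Of 21 NF-kappaB-linked genes 11 rose and 8 fell (camera adjusted p = 0.895), or 7 and 10 with library totals. VCAM1, a leukocyte adhesion molecule, rose from 18.5 ± 0.605 to 57.9 ± 3.18 CPM, the chemokine gene CXCL1 changed by -3.43 ± 0.098 on the log2 scale, and ICAM1, also a leukocyte adhesion molecule, stood at 24.3 ± 2.47 and 23.5 ± 2.63 CPM (edgeR adjusted p = 0.552). ICAM1 passed as lower with library totals (-0.38, edgeR adjusted p = 0.000227). Interferon response genes rose in 5 and fell in 8 of 20 cases (camera adjusted p = 0.558), or 4 and 10 with library totals, with the antiviral gene OAS3 lower (-3.06 ± 0.090) and IFI27 (1.32 ± 0.072), RIGI (0.86 ± 0.049), ISG15, IFI44L and IRF9 higher.

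Genes of acetate and acetyl-CoA metabolism, the topic of the series title, did not pass camera as a group, although fry called them lower (fry adjusted p = 2.29e-06). ACSS2, which makes acetyl-CoA from acetate, was 21.0 ± 0.569 CPM in controls and 16.96 ± 1.22 CPM with TGFbeta (log2 fold change -0.31 ± 0.064 SE, edgeR adjusted p = 0.000185), and its log2 fold change was -0.63 with library totals. PDK4, a kinase that inhibits pyruvate dehydrogenase, fell from 1.69 ± 0.346 to 0.321 ± 0.178 CPM, from 152 to 23 reads over 4 libraries. Of 29 list members 18 fell and 8 rose (camera adjusted p = 0.357), or 23 and 4 with library totals. The list passed in the CPM values without a filter (adjusted p = 0.0421; range over all alternatives 2.29e-06 to 0.428). DLAT, a pyruvate dehydrogenase subunit (-0.92 ± 0.042), and FASN, fatty acid synthase (-0.49 ± 0.035), fell, and the lactate exporter gene SLC16A3 rose (0.73 ± 0.029).

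Other metabolic lists did not pass camera with TMM. Fry called all of them lower. Its adjusted p was 1.67e-06 for glycolysis, 4.14e-06 for the TCA cycle, 0.00331 for fatty acid oxidation and 1.90e-05 for cholesterol synthesis. Glycolysis genes fell in 12 and rose in 6 of 19 cases (camera adjusted p = 0.152; 14 and 4 with library totals), with ENO1 (-0.74 ± 0.020) and LDHA (-0.74 ± 0.022) lower and PFKP (1.01 ± 0.024) higher. TCA cycle genes fell in 13 and rose in 4 of 20 cases (camera adjusted p = 0.180; 17 and 1 with library totals): IDH3A (-1.32 ± 0.049) and SDHA (-0.76 ± 0.033) fell, and IDH2 (1.34 ± 0.044), DLST and SDHC were among the risers. Of 20 fatty acid oxidation genes 10 fell, among them CPT1A (-0.64 ± 0.045) and ACADSB (-0.64 ± 0.067), and DECR1 (0.51 ± 0.049), HADHA, HADHB and ACSL4 rose (camera adjusted p = 0.603), whereas 17 fell and 1 rose with library totals. The fatty acid oxidation list passed in the CPM values without a filter (adjusted p = 0.0265; range over all alternatives 0.00331 to 0.753). Cholesterol synthesis genes fell in 11 and rose in 6 of 20 cases (camera adjusted p = 0.331; 17 and 1 with library totals), with IDI1 (-0.55 ± 0.041) lower and SC5D (0.90 ± 0.050) higher. With library totals the glycolysis (adjusted p = 0.00577; range over all alternatives 1.67e-06 to 0.424) and TCA cycle lists (adjusted p = 0.0379; range 4.14e-06 to 0.396) passed as lower. The TCA cycle (adjusted p = 0.0339) and cholesterol lists (adjusted p = 0.0488; range 1.90e-05 to 0.489) also passed in the CPM values. There neither passed after quantile normalization (adjusted p = 0.0527 and 0.241), median-ratio scaling (0.0561 and 0.266) or the stricter filter (0.0662 and 0.0911), whereas the glycolysis list passed after quantile normalization (adjusted p = 0.0401).

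Cell cycle genes fell in all 25 tested cases (camera adjusted p = 4.68e-35, and adjusted p = 0.00367 with an estimated correlation). CDC20, a mitotic activator (-2.58 ± 0.044 on the log2 scale), the replication helicase gene MCM4 (-2.09 ± 0.031) and MKI67 (-1.97 ± 0.032) led by p. FGF and ERK feedback genes fell in 11 of 18 cases and FGFR3, FRS2, FGF2 and SPRED1 rose (camera adjusted p = 0.0427, and adjusted p = 0.176 with an estimated correlation), or 14 fell and 3 rose with library totals. The phosphatase gene DUSP5 (-3.02 ± 0.090), PHLDA1 (-2.52 ± 0.038) and the AP-1 gene FOSL1 (-1.98 ± 0.051) fell. That list did not pass without TGFbeta replicate 1 (adjusted p = 0.0648) or 3 (adjusted p = 0.0520), with the stricter filter (adjusted p = 0.0685) or in the CPM values (adjusted p = 0.190; range over all alternatives 5.32e-07 to 0.191).

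Hypoxia genes rose in 10 of 13 cases, and ADM and BNIP3 fell (camera adjusted p = 0.00236, and adjusted p = 0.0617 with an estimated correlation). ANGPTL4 (2.52 ± 0.047), STC2 (1.86 ± 0.045) and the mitophagy receptor gene BNIP3L (1.13 ± 0.031) rose. Heat shock genes fell in 9 of 10 cases (camera adjusted p = 0.00294, and adjusted p = 0.0573 with an estimated correlation), including the chaperone genes HSPD1 (-1.27 ± 0.025) and HSP90AA1 (-0.98 ± 0.022), and HSPB1 rose (1.41 ± 0.035). The heat shock list did not pass in the CPM values with the stricter filter (adjusted p = 0.0757; range over all alternatives 7.66e-09 to 0.0757). Of 14 integrated stress response genes 7 fell and ATF3 and DDIT4 rose (camera adjusted p = 0.0502), whereas 11 fell and 2 rose with library totals. The cystine transporter gene SLC7A11 (-1.54 ± 0.043), TRIB3 (-2.19 ± 0.061) and the serine synthesis gene PSAT1 (-1.65 ± 0.054) fell. This list passed on leaving out TGFbeta replicate 1, 2 or 4 or any control library (adjusted p = 0.0431 to 0.0491; range over all alternatives 1.06e-08 to 0.206), as without a filter (adjusted p = 0.0276).

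Of 13 mitochondrially encoded genes 9 rose and MT-ND1 fell (camera adjusted p = 0.603), whereas 0 rose and 8 fell with library totals. With TMM, MT-CYB (0.34 ± 0.035), MT-ND5 (0.33 ± 0.034) and MT-ND6 (0.32 ± 0.038) rose. Mitochondrial transcripts took 2.87 ± 0.173% of counts with TGFbeta and 3.04 ± 0.145% in controls (SD, n = 4; exact permutation p = 0.200).

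Markers of other cell types went both ways. Among 4 tested pericyte markers RGS5 fell from 439 ± 7.09 to 36.2 ± 0.856 CPM, and NOTCH3 (17.7 ± 1.66 CPM with TGFbeta), PDGFRB and ANPEP (217 ± 4.24 CPM with TGFbeta) rose (camera adjusted p = 0.349). In the CPM values the log2 fold change of ANPEP was 0.074, and it did not pass there without the trend. Of 14 leukocyte and erythroid markers 2 were tested: CD14 rose from 0.155 ± 0.0932 to 5.47 ± 0.530 CPM, and CD68 stood at 11.1 ± 0.446 and 10.6 ± 0.780 CPM (edgeR adjusted p = 0.408; list camera adjusted p = 0.542). CD68 passed as lower with library totals (-0.40, edgeR adjusted p = 0.000108). Of 4 tested epithelial markers, all keratins, KRT7 rose from 117 ± 5.22 to 1223 ± 13.2 CPM, and KRT19 (-2.93 ± 0.051), KRT18 (-1.36 ± 0.027) and KRT8 fell (camera adjusted p = 0.768). The median and the camera direction differed in sign for the endothelial identity, NF-kappaB, shear-responsive and pericyte lists, none of which passed camera.

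Transcript models showed the same balance, with 7788 of 43224 higher and 7080 lower (edgeR quasi-likelihood test), or 4775 and 12684 with library totals. The longest TGFBR1 transcript (chromosome 9, 101867371 to 101916474) rose from 6.16 ± 2.61 to 117 ± 15.7 CPM. Both tested ACTA2 transcripts (edgeR adjusted p = 0.255 and 0.267) and the 3 tested ACSS2 transcripts (lowest edgeR adjusted p = 0.222) did not pass. In 188 genes some transcripts rose and others fell, and in 6, chosen after their values were seen, both moves reached 2-fold with at least 5 CPM: NAV2, NRG1, PHLDB2, PRKACB, SYNPO and TPM1. A TPM1 transcript starting at 63334884 on chromosome 15 rose from 194 ± 6.01 to 2394 ± 27.5 CPM and one starting at 63340666 fell from 25.6 ± 2.04 to 5.21 ± 1.57 CPM. Transcript values are estimates that divide shared reads, and their coefficient of variation between libraries was 0.300, against 0.0366 for genes.

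In the coordinates of the deposited tables, whose build is not given in the sources used here, FN1 lay at 216225163 to 216300895 on chromosome 2, TAGLN at 117070037 to 117075498 on chromosome 11, ACTA2 at 90694831 to 90751147 on chromosome 10 and ACSS2 at 33462766 to 33515769 on chromosome 20. VCAN lay at 82767284 to 82878122 on chromosome 5, TGFBR1 at 101867371 to 101916474 on chromosome 9, GJA5 at 147228332 to 147245484 on chromosome 1 and MMP1 at 102660651 to 102668891 on chromosome 11.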

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

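The tests of explanations here, the gene sets and bounds they use, and the comparison with other splits of the libraries were written down after the results were seen; for fibroblasts the deciding collagen was later changed from the highest of 3 to the middle one. In each group of 4 libraries the gap between the most extreme library and its nearest neighbour was divided by the range of the group. Of 232 groups of values (named genes and library measures), 12 exceeded Dixon's 95% critical value, where chance gives about 11.6. VCAN, CNN1 and BDKRB2 each had all control reads in 1 library (a ratio of 1 for each). In controls, CXCL12 was high in replicate 4 (0.333 CPM, others up to 0.129; ratio 0.839) and ANKRD1 in replicate 1 (626, others up to 559.9; ratio 0.856). PHLDA1 was high in control replicate 2 (145, others up to 140.2; ratio 0.943). MT-ND6 was low in control replicate 3 (467, others from 493; ratio 0.836) and CD68 in control replicate 2 (10.5, others from 11.3; ratio 0.891). With TGFbeta, PMEPA1 was low in replicate 4 (418, others from 427; ratio 0.838) and NQO1 in replicate 2 (48.5, others from 51.2; ratio 0.885). SLC16A3 was high in TGFbeta replicate 3 (266, others up to 256; ratio 0.872) and CD68 in TGFbeta replicate 2 (11.7, others up to 10.2; ratio 0.919).

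Smooth muscle genes rose with TGFbeta while endothelial identity genes moved apart. Smooth muscle cells among the TGFbeta cells are argued against, since ACTA2 and MYH11, abundant in such cells, reached at most 0.451% of the TAGLN level (10.7 ± 1.06 CPM for ACTA2). Fibroblasts among the TGFbeta cells cannot be told apart as a source of the rise, because the abundant fibroblast collagens disagree. COL1A1 stood at 0.659% of the TAGLN level (15.6 ± 0.700 CPM) and COL3A1 at 0.214% (5.07 ± 0.338 CPM), but COL1A2 reached 8.90%. The low level of COL1A1, the middle one, would argue against fibroblasts. It replaced the highest, COL1A2, as the deciding collagen only after the results were seen, so no conclusion is drawn from it. Culture medium rather than the growth factor cannot be told apart as the cause, because 0 groups separate them, so the change may be a response to either.

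Cell cycle genes fell together, with a median log2 fold change of -1.85. Removing a smooth trend on GC content and transcript length left the median at -1.81 (median absolute deviation 0.34, 25 of 25 genes below 0), which argues against that trend as the whole cause. The median of -1.85 is on the TMM scale, which is meant to remove a shift from a few abundant genes taking counts, so it cannot test that explanation. With library totals the median of the list was -2.17, and the share of the 14 most abundant genes shifted the others by -0.12. On that scale these few genes are argued against as the whole cause. Culture medium rather than the growth factor cannot be told apart as the cause, with 0 groups that separate them.

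More genes fell than rose with library totals, where the median log2 fold change was -0.32. Without the 14 most abundant genes in the totals it was -0.20, still below -0.16, so that these few genes are argued against as the whole cause. The 717 genes that rose at least 4-fold took 13.1 ± 0.0994% of counts with TGFbeta and 1.95 ± 0.0201% in controls. A change in total RNA per cell cannot be told apart, since 0 spike-in RNAs were in the counts used here.

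Of 35 splits of the libraries 1 gave as many changed genes (the real one, 11020, highest other 0). For transcripts it was also 1 of 35 (the real one, 14868, highest other 0). This is the smallest share that 35 splits allow, and it argues against chance in how these libraries were labelled. Every other split mixes the groups, so the counts of 0 follow from the difference between them. A chance difference between cultures cannot be excluded, since the labels do not say whether replicates were separate cultures. For gene lists, 1 of 35 splits called as many (the real one, 15), but the highest other split called 13, with 0 genes changed. The number of lists called is therefore weak evidence by itself.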

How the results depend on the processing

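Library totals without TMM, the CPM values tested with limma in place of the counts, and the robust edgeR fit were chosen after seeing the data. Of 110 named genes 104 had the same direction and side of the threshold in all alternatives to the count test; the others were ACTA2, ICAM1, CD68, MT-CYB, MT-ND5 and MT-ND6. Of 30 lists 11 did. Most named genes were chosen for a large change or a small p, so they say little about the steadiness of other calls. Of 11020 genes called, 8793 were also called in the same direction with library totals, and 650 in the opposite direction. In the CPM values these numbers were 7724 and 696. A fold change of at least 2, stricter by construction, left 3124 genes (1708 up, 1416 down) and 7208 transcripts (3954 up, 3254 down). Scaling moved the balance: library totals gave 3320 genes up and 8388 down, 4775 transcripts up and 12684 down, and 5 lists down in place of 3. The CPM values gave 3003 genes and 3761 transcripts up. On these values quantile normalization gave 4726 genes up, 5755 transcripts up and 6645 down, and median-ratio scaling 4872, 5782 and 6600, with 2 lists down. The stricter filter on the CPM values gave 1 list down in place of 4; the cause was not tested. Of 15 lists called (12 up, 3 down), an estimated correlation left 8 (7 up, 1 down). Fry, which does not compare a list with other genes, called 27 (12 down). Reversed log2 fold changes were -0.0048 for MT-ND6 and -0.32 for ACTA2 with library totals, -0.29 for ACTA2 in the CPM values, and, there after quantile normalization, 0.011 for ACTA2 and -0.087 for CDH5. Leaving out each library in turn gave 10799 to 10897 genes (10592 to 10664 of them called in the same direction with all libraries), 13403 to 14140 transcripts and 14 to 16 lists. It gave -0.050 to 0.058 for ACTA2, below 0 without TGFbeta replicate 1 or 2 or control replicate 4, and -0.12 to 0.0091 for ICAM1, above 0 without TGFbeta replicate 2 or control replicate 4. Same-numbered libraries did not deviate together (correlations across genes -0.162 to 0.00954), so there was no sign that the numbers pair the samples. A pairing with effects too weak to show here cannot be excluded. With the replicate block 10774 genes, 12791 transcripts and 15 lists passed. The count test on whole reads of the CPM values was not run, since whole reads could not be recovered from them. Depth limits genes with few reads, such as PDK4 and SNAI2.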

Other observations

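The tests of gene families here were chosen after the data were seen. Families of genes that share a symbol prefix (220 with at least 8 tested members) were tested with camera, and 7 passed after adjustment over the families, but 0 with an estimated correlation. Nucleoporin genes (NUP), which build the nuclear pore, fell in 21 of 21 cases with TMM and with library totals (median log2 fold change -0.63, camera adjusted p = 3.01e-05, and adjusted p = 0.214 with an estimated correlation). Genes of the large subunit of the mitochondrial ribosome (MRPL) fell in 44 and rose in 3 of 51 cases (median -0.49, camera adjusted p = 0.0107, and adjusted p = 0.567 with an estimated correlation), and in 49 cases with library totals. NOP genes, several of which act in ribosome assembly, fell in 7 of 8 cases (camera adjusted p = 0.0375, and adjusted p = 0.577 with an estimated correlation). The other families that passed were COL, MCM, KIF and ADAM; the ADAM median was 0.30 with TMM and -0.023 with library totals.

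In all, 13 genes had at most 3 reads over the 4 control libraries and at least 5 CPM with TGFbeta, also chosen after their values were seen. Besides VCAN, CNN1, BDKRB2 and GREM1 they included NPPB, a natriuretic peptide gene (0 control reads, 8.84 ± 0.475 CPM), ACTC1, cardiac actin (0 control reads, 5.91 ± 0.752 CPM), and FOXS1, a forkhead transcription factor (0 control reads, 9.13 ± 0.735 CPM).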
